A study of Homo sapiens with 7 samples.

How the data were processed

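HiCAR was carried out on 7 samples, 3 of the human embryonic stem cell line H1 and 4 of the B-lymphoblastoid line GM12878, and samples were grouped by the cell line in the labels. Per the labels and the series design text, formaldehyde-fixed cells were treated with Tn5 carrying an adaptor, cut with CviQI, ligated in place, cut again with NlaIII, circularised and amplified. Per the submitters' processing notes, the aligner was BWA and the genome builds were hg38 and, for some GM12878 samples, also mm10; the version of BWA is not given in the sources used here. The processed files name MAPS, a caller of long-range interactions, with no version given in the sources used here. Each line had 1 deposited list of called pairs of 5-kb bins, and another deposited list of 10-kb bins was filed under GM12878 replicate 1. The name of that last file writes the cell line differently from the label, and the label was followed. Which replicates were pooled for the lists is not given in the sources used here.

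The authors' lists give whole-number read counts per called pair, which are not normalised, per the file headers. The expected reads of each pair are the signal of the authors' background model, per the file headers. The false discovery rate of each pair, a p-value adjusted by the authors' caller per the file headers, lay under 0.01 for all deposited pairs. The deposited lists also give the size of the cluster a pair belongs to and a −log10 of the cluster's combined p-value, per the file headers. Called pairs of the deposited lists lay on the 22 autosomes, so genes on other chromosomes were not measured. The depth per sample is unknown, and the precision of a value is set by the number of called pairs and by their reads. Because only called pairs are listed, a gene without a call is described as having no called interaction, and no lower limit on a fold is given for it. A bin pair called in 1 line and not in the other can also reflect how easily it passed the caller's threshold there.

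Gene coordinates on hg38 came from the exon positions in the deposited gene table, whose file name names featureCounts. Of its 60675 gene identifiers, 56558 matched a symbol and 39846 a gene type in a RefSeq table of the assembly GRCh38.p14, used for names and types only. The start of a gene was the outermost annotated 5′ end on its strand, and the promoter was the 5-kb bin holding it, for 18282 protein-coding genes. Starts further inside a gene were not counted, so a promoter in use there can be missed. Values in 2 count columns of that gene table were not used, since their names give no cell line and match no single listed sample. Expression was therefore not analysed here, and neither was the orientation of CTCF motifs, which needs a genome sequence.

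Interactions were called shared when both ends lay within 1 bin of each other. Shares carry exact binomial (Clopper-Pearson) 95% intervals, and counts per gene exact Poisson 95% intervals. These cover counting error only, and reads were not independent molecules. As a background, every pair was moved by a random offset of 100 kb to 5 Mb along its chromosome with its span kept, in 100 draws. For each gene list, the interactions of its members' promoters were summed per line, so that a pair joining members or meeting a bin shared by members counted for each of them, and the ratio of GM12878 to H1 was divided by that of all protein-coding promoters. The interval of that log2 ratio came from the exact binomial interval of the GM12878 share. Per gene, interactions were scaled to equal totals with a pseudocount of 1, and the median log2 ratio of a list was placed among 10000 random lists of the same size matched on 10 classes of mean interaction number. Since 12057 of the 18282 genes had no call in either line, the lower classes held only such genes, divided arbitrarily. The class above these mixed genes without a call and genes with the smallest numbers of calls. A member with a single call could thus be matched to genes with none. No p-value was computed between lines, since each had 1 list of 5-kb bins.

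The 11 gene lists, with 279 genes, and the rule for named genes were fixed before the data were examined. The rule named, per list, the 2 members with the largest scaled excess in each line, the 8 bins with the largest excess genome-wide in each line, the 3 bins with most interactions per line, and a fixed set of genes including POU5F1, SOX2, NANOG, PAX5 and EBF1 whatever their values. Some genes that the rule names are not reported here. For pluripotency, B cell and developmental transcription factor members so named, the interaction with the highest reads over expected and the longest were given. Other members named are marked as named after their values were seen, and 6 further gene lists were chosen after seeing the data.

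Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with figures drawn in matplotlib 3.10.9. The list ratio was tested on simulated data over 18282 genes, where a true ratio of 2 gave a median of 2.07 and a true ratio of 4 gave 3.84, and the interval held the true value in 98 and 97 of 100 lists. Simulated counts were drawn independently per gene, with unchanged genes as the baseline. This coverage therefore does not extend to the neighbouring pairs and shared bins of the deposited lists. The shared share was tested on 34399 simulated pairs, where true shares of 20.2% and 50.2% gave 20.8% and 50.4%. Simulated shared pairs lay within 1 bin by design, so this checks the counting only. Alternatives were a false discovery rate under 0.001, leaving out pairs that stand alone, identical bins or bins within 2 of each other, equal numbers of pairs, neighbouring bins added to the promoter, all annotated genes, summed reads and leaving out the member with most interactions. Chosen after seeing the data were pairs up to 2 Mb apart, pairs at least 20 kb apart, clusters counted once per gene, pairs counted once per list and, for the further lists, leaving out the 1 or 2 members with most interactions.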

Results

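HiCAR libraries were made from H1, a human embryonic stem cell line, in 3 samples, and from GM12878, a B-lymphoblastoid cell line, in 4 samples. In HiCAR the transposase Tn5 tags accessible chromatin in cross-linked cells, and each tagged site is ligated to DNA that lies near it in the nucleus. A called interaction was a pair of 5-kb genome bins joined by more reads than a background model expected. Each line had 1 list of such pairs, so values are given without a replicate error, no p-value is given across genes, and intervals cover counting error only. The H1 list held 34399 interactions and 751520 reads, and the GM12878 list held 48516 interactions and 1363217 reads. The total sequencing depth of the libraries is unknown, because the lists hold only called pairs.

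The first comparison asked how many contacts of accessible chromatin were called in each line and how far they reached. GM12878 had 1.41 times as many interactions as H1 (exact 95% interval 1.39 to 1.43). Interactions spanned a median of 155 kb in H1 (interquartile range 80 to 265 kb) and 145 kb in GM12878 (75 to 255 kb). The share spanning more than 100 kb was 67.7% in H1 (exact 95% interval 67.2 to 68.2%) and 65.1% in GM12878 (64.7 to 65.5%). A median interaction rested on 17 reads in H1 (interquartile range 13 to 25) and on 20 reads in GM12878 (14 to 34). The reads of a median interaction exceeded the expected reads 4.85-fold in H1 and 4.15-fold in GM12878. Neighbouring interactions formed 9690 clusters in H1 and 11860 in GM12878, and 2621 and 2698 interactions stood alone.

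The 3 bins with the most interactions lay at different loci in the lines. In H1 the 3 highest all lay in the histone gene cluster of chromosome 6. The bin at 27810001 to 27815000, which holds the starts of the histone genes H2AC14 and H3C10, had 32 interactions in H1 and 17 in GM12878. The bin at 27835001 to 27840000, with H2AC15 and H2BC15, had 30 and 9. The third, at 27790001 to 27795000, lay between genes 15.4 kb from the start of H2BC13 and had 28 and 13. In GM12878 the 3 highest bins lay on chromosome 1 between protein-coding genes. The bin at 234495001 to 234500000, 18.4 kb from the start of TARBP1, had 37 interactions in GM12878 and 14 in H1. The bin at 160430001 to 160435000, 31.9 kb from the start of VANGL2, had 35 against 1, and the bin at 235075001 to 235080000, 51.4 kb from the start of TOMM20, had 33 against 1. All coordinates are those of the human genome build hg38.

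The lines shared a minority of their interactions, and promoters took part in the shared ones more often. Of the H1 interactions, 37.8% (37.2 to 38.3%) had a GM12878 interaction with both ends within 1 bin, and 30.4% (30.0 to 30.8%) of the GM12878 interactions had such a partner in H1. Interactions with a protein-coding gene start at both ends were shared in 43.5% of H1 cases (40.01 to 47.1%), those with 1 such end in 40.1% (39.0 to 41.3%), and those with none in 37.0% (36.4 to 37.6%). In GM12878 the same classes gave 39.6% (36.2 to 43.04%), 33.8% (32.8 to 34.8%) and 29.4% (29.0 to 29.9%). After all pairs were moved by random offsets along their chromosomes, the median shared share over 100 draws was 1.06% for H1 and 0.812% for GM12878. Each pair was moved on its own, without regard to accessibility and without keeping clusters together. This background therefore cannot separate shared contacts from accessible sites that both lines have. Short contacts were shared least. Among H1 interactions under 50 kb 18.2% were shared, against 43.3% from 50 to 200 kb and 39.6% at 200 kb or more. For GM12878 these shares were 14.0%, 33.0% and 34.3%. Shared H1 interactions had a median of 5.31 times the expected reads and unshared ones 4.55 times, and in GM12878 these values were 5.28 and 3.69. Median reads were 17 for shared and 16 for unshared interactions in H1, and went the other way in GM12878, with 18 and 21. Across the 7777 pairs called in identical bins of both lines, Spearman rho between lines was 0.69 for reads over expected and 0.54 for reads. Pairs are not independent replicates. Such a pair has the same span in both lines, and how much of either rho comes from span was not tested. The share depended on the matching rule, with 22.6% of H1 and 16.0% of GM12878 interactions found in identical bins.

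Promoters of protein-coding genes took part in a slightly higher share of interactions in H1 than in GM12878, as they did after random moves. A start of a protein-coding gene lay at 1 or both ends of 22.6% of H1 interactions (22.2 to 23.0%) and of 19.6% of GM12878 interactions (19.2 to 19.96%). Randomly moved pairs met such a start in a median of 9.07% of H1 and 7.64% of GM12878 cases, with a maximum over 100 draws of 9.39% and 7.94%. This background was also higher in H1, so the difference in share alone does not show a stronger preference for promoters there. Both ends held a start in 2.25% of H1 interactions (2.10 to 2.41%) and 1.67% of GM12878 interactions (1.56 to 1.79%). Of 18282 protein-coding genes, 1921 had a called promoter interaction in both lines, 1931 in H1 alone and 2373 in GM12878 alone. With the bins next to the gene start included, the shares with a promoter were 41.8% in H1 and 39.9% in GM12878.

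The next comparison asked which groups of genes had more promoter contacts in which line, with 11 gene lists fixed before the data were examined. All protein-coding promoters together had 9655 interactions in H1 and 11668 in GM12878, a ratio of 1.21, and each list is given relative to that ratio. Promoters of B cell, NF-κB response and MHC class II genes had more interactions in GM12878. Promoters of pluripotency genes, developmental transcription factors, HOX genes and alpha protocadherins had more in H1. HiCAR reads depend on the accessibility of a promoter, and a difference in accessibility between the lines was not tested for any list. Members are counted as higher in a line after scaling to equal totals, so that a gene with the same small count in both lines counts as higher in H1. Interactions of neighbouring bins are not independent, which the intervals do not cover. A member with 1 interaction in GM12878 and none called in H1 has a log2 ratio of 0.94, and a member with 1 in H1 only has −1.07. A list median at these values is thus that of a single call. Random lists could match such members to genes without a call, so percentiles place a list only roughly.

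**Figure D1:**
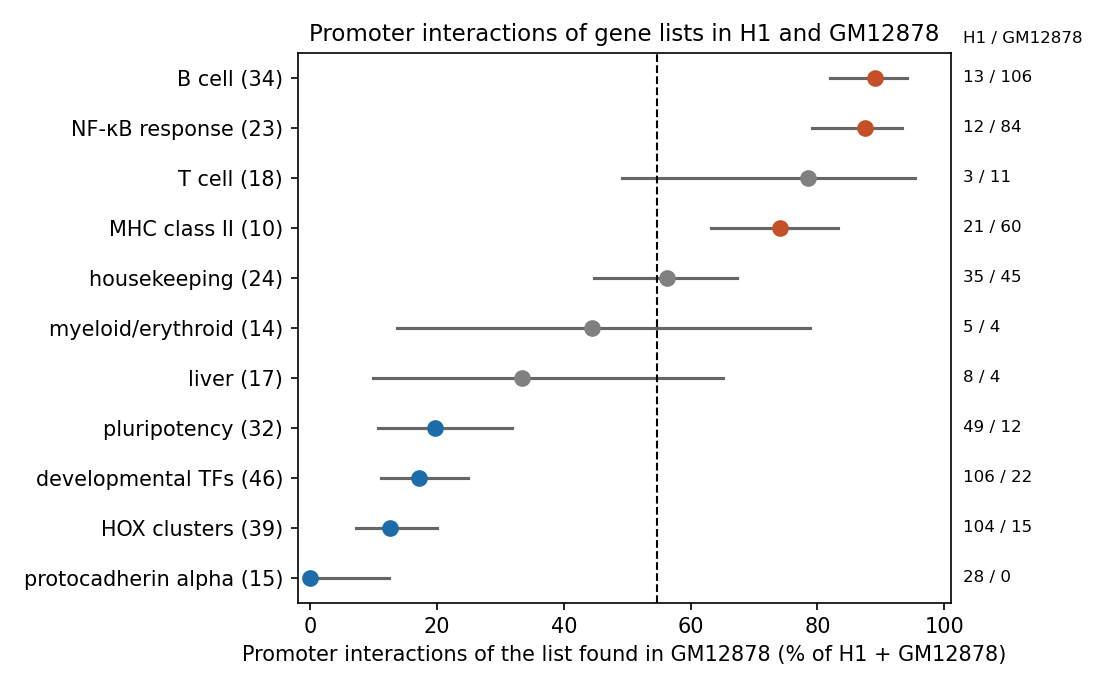
Share of each list's promoter interactions that was found in GM12878, in percent of the H1 and GM12878 interactions together. Points are lists (measured genes in parentheses), bars exact 95% binomial intervals, the dashed line the share over all protein-coding promoters, and the numbers at the right the interactions in H1 and GM12878. Red and blue points mark lists whose interval lies above or below the dashed line, from B cell genes with 13 and 106 interactions to alpha protocadherins with 28 and 0.

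B cell genes had 106 promoter interactions in GM12878 and 13 in H1 over 34 measured genes. Relative to all promoters this was 6.75-fold more in GM12878, a log2 ratio of 2.75 (95% interval 1.92 to 3.71). The ratio was 3.75 with the reads of the interactions summed, and 1.90 (0.83 to 3.13) with each cluster of neighbouring interactions counted once per gene, an alternative chosen after seeing the data. The gene encoding PAX5, the transcription factor that maintains B cell identity (chromosome 9, 36833275 to 37034185, minus strand), had 21 interactions in GM12878 (Poisson 95% interval 13.0 to 32.1) and 4 in H1 (1.09 to 10.2). CIITA, the master activator of MHC class II genes (chromosome 16, 10877198 to 10932281), had 11 in GM12878 (5.49 to 19.7) and no called interaction in H1. The CIITA interactions formed 2 clusters. Of the 34 genes, 19 were higher in GM12878, 3 in H1, and 12 had no called interaction in either line. The 3 were EBF1, an early B lineage transcription factor, with 5 in H1 and 4 in GM12878, and CD40 and CD74 with 1 in each line, CD74 being named after its values were seen. The direction turned for EBF1 with neighbouring bins, at 64.7% in GM12878, and for CD40 with summed reads, at 91.5%. The median log2 ratio of the list's members was 0.94, the value of a gene with 1 interaction in GM12878 and none called in H1. It lay above that of each of 10000 random lists of equal size matched on interaction number (percentile 100).

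Single contacts of the PAX5 promoter reached far beyond the gene. The one with the highest reads over expected joined it to 37330001 to 37335000 on chromosome 9, which lay inside ZCCHC7 without touching an annotated exon. This contact spanned 300 kb and had 35 reads against 6.02 expected. The longest PAX5 contact in GM12878 spanned 385 kb and ended at 37415001 to 37420000, 5.17 kb from the start of GRHPR. The strongest CIITA contact was also its longest, at 140 kb, and joined the promoter to 10735001 to 10740000 on chromosome 16, between genes and 6.29 kb from the start of NUBP1, with 67 reads against 15.0 expected. In H1 the strongest EBF1 contact spanned 385 kb and ended at 158710001 to 158715000 on chromosome 5, over an exon of EBF1 itself, with 11 reads against 1.63 expected. The longest EBF1 contact in H1 spanned 400 kb. The CD40 contact in H1 spanned 210 kb and ended between genes, 19.0 kb from the start of CDH22, with 11 reads against 2.51 expected.

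NF-κB response genes, many of which are switched on in lymphoblastoid cells by the Epstein-Barr virus protein LMP1, had 84 interactions in GM12878 and 12 in H1 over 23 genes. The relative excess in GM12878 was 5.79-fold (log2 2.53, 1.65 to 3.54). NFKBIA, the inhibitor of NF-κB, had 11 interactions in GM12878 and no called interaction in H1, and BIRC3, an inhibitor of apoptosis, had 10 and none. They formed 3 clusters for NFKBIA and 4 for BIRC3. Of the 23 genes 16 were higher in GM12878, 4 in H1 and 3 had no called interaction. The 4 were TNFAIP2 and TRAF1, with 1 interaction in H1 and none called in GM12878, and ICAM1 with 5 and 6 and CXCR4 with 1 and 1, the last pair being named after their values were seen. The median log2 ratio of 0.94 lay at percentile 99.3 of the random lists.

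MHC class II genes, which encode the antigen-presenting molecules of B cells, had 60 interactions in GM12878 and 21 in H1 over 10 genes, a 2.36-fold relative excess (log2 1.24, 0.50 to 2.03). HLA-DRA (chromosome 6, 32439842 to 32445046) had 30 in GM12878 (20.2 to 42.8) and 7 in H1 (2.81 to 14.4), and HLA-DRB1 had 10 and 4. In the other direction HLA-DPA1 had 4 in H1 and 1 in GM12878, and HLA-DOA had 6 and 5. The direction of HLA-DPA1 turned with neighbouring bins included, where 63.6% of its interactions were in GM12878. Of the 10 genes 7 were higher in GM12878 and 2 in H1, and the median log2 ratio of 0.94 lay at percentile 97.52. The excess rested on HLA-DRA in part, since without it the log2 ratio was 0.83 with an interval that held 0 (−0.13 to 1.86). With each cluster of neighbouring interactions counted once per gene, an alternative chosen after seeing the data, it was 0.95 (−0.32 to 2.36).

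Pluripotency genes had 49 promoter interactions in H1 and 12 in GM12878 over 32 measured genes. This was 4.93-fold more in H1 relative to all promoters (log2 ratio of GM12878 to H1 −2.30, −3.35 to −1.37). OTX2, a homeobox gene of pluripotent and anterior neural cells (chromosome 14, 56799905 to 56810479, minus strand), had 8 in H1 (3.45 to 15.8) and no called interaction in GM12878, and FGF2, a growth factor that maintains human embryonic stem cells, had 7 and none. They formed 5 clusters for OTX2 and 2 for FGF2. SOX2 had 4 interactions in H1 and NANOG 3, with none called in GM12878, both being core pluripotency transcription factors. POU5F1, the third core factor, had no called interaction in H1 and 1 in GM12878, counted at the outermost annotated start of the gene. Of the 32 genes 14 were higher in H1, 5 in GM12878 and 13 had no called interaction. The other members higher in GM12878 were CDH1 and TERF1, each with 2 interactions there and none called in H1, and JARID2 with 5 and 3 and LEFTY2 with 1 and none, the last pair being named after their values were seen. Because 13 members had no call, the median log2 ratio of the list was 0, unlike the summed ratio. The median of 99.3% of the random lists equalled it, so it could not place this list.

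The strongest OTX2 contact in H1 joined its promoter to 57180001 to 57185000 on chromosome 14, between genes and 86.4 kb from the start of AP5M1, over 370 kb, with 15 reads against 2.33 expected. The longest OTX2 contact spanned 380 kb. The strongest FGF2 contact spanned 65 kb, to 122760001 to 122765000 on chromosome 4, with 42 reads against 9.51 expected, and its longest spanned 80 kb. In GM12878 the CDH1 promoter met a bin inside the same gene and outside its exons at 40 kb, with 26 reads against 9.68 expected. The strongest TERF1 contact there spanned 160 kb, ended between genes 43.4 kb from the start of SBSPON and had 20 reads against 5.83 expected, while the longest spanned 165 kb.

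Transcription factors of embryonic development had 106 promoter interactions in H1 and 22 in GM12878 over 46 genes. The relative excess in H1 was 5.82-fold (log2 −2.54, −3.28 to −1.87), and 32 members were higher in H1, 2 in GM12878 and 12 had no called interaction. SIX3, a homeobox gene of forebrain and eye development (chromosome 2, 44941898 to 44946077), had 14 in H1 (7.65 to 23.5) and no called interaction at its start bin in GM12878. GM12878 did have interactions close by, from bins centred at 44952500 and 44957500. Their far ends were centred at 44392500 and 44477500, bins that the SIX3 start bin also met in H1. The contrast at SIX3 therefore depends on taking a single bin as the promoter. The 2 members higher in GM12878 were NEUROG2, a proneural factor, with 12 (6.20 to 21.0) against 2, and TBXT, the mesoderm factor brachyury, with 1 against none called. The median log2 ratio of the list was −1.07, at percentile 0.005 of the random lists.

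The strongest contact of SIX3 in H1 spanned 465 kb and met 44475001 to 44480000 on chromosome 2, inside CAMKMT and outside its exons, with 21 reads against 2.45 expected. The longest SIX3 contact spanned 580 kb and ended on the bin that holds the starts of CAMKMT and PREPL. The strongest NEUROG2 contact in GM12878 spanned 415 kb, with 14 reads against 1.93 expected, and ended between genes, 42.9 kb from the start of FAM241A, while the longest spanned 420 kb. The single TBXT contact in GM12878 spanned 35 kb and had 34 reads against 14.9 expected.

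**Figure D2:**
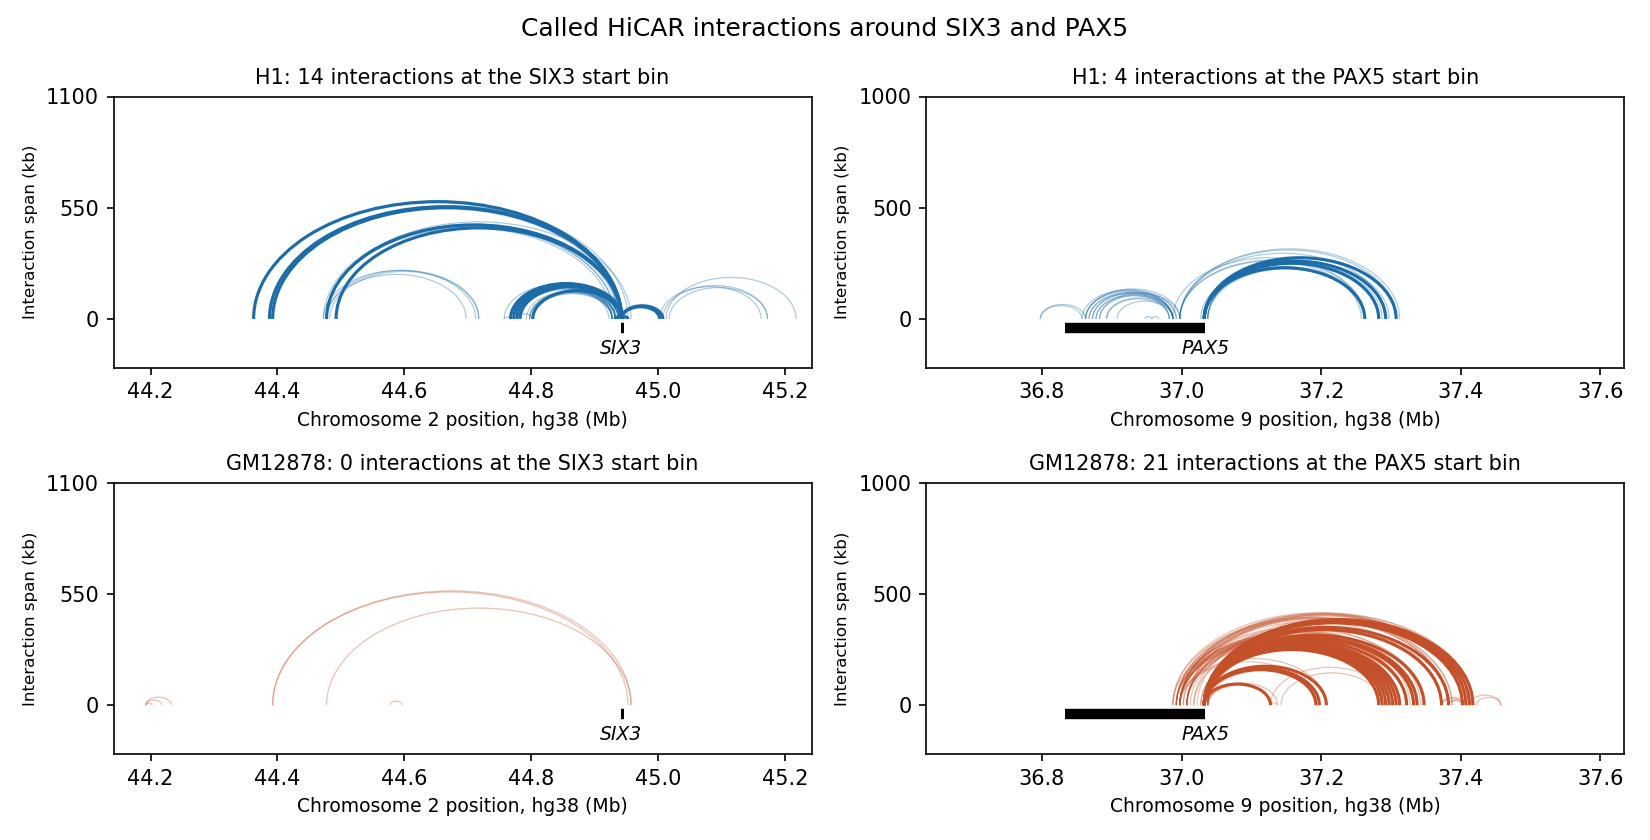
Called interactions around SIX3 on chromosome 2 and PAX5 on chromosome 9, each arc joining the centres of a pair of 5-kb bins, with hg38 position in Mb on the horizontal axis and the span of the interaction in kb on the vertical axis. Thick arcs end on the bin of the gene start, thin arcs elsewhere, and black bars are the genes. SIX3 had 14 thick arcs in H1 and 0 in GM12878, and PAX5 had 4 in H1 and 21 in GM12878.

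HOX genes, the clustered homeobox genes that pattern the body axis, had 104 promoter interactions in H1 and 15 in GM12878 over 39 genes. The relative excess in H1 was 8.38-fold (log2 −3.07, −3.95 to −2.28), with 26 members higher in H1, 1 in GM12878 and 12 without a call. HOXC5 had 14 interactions in H1 and 1 in GM12878, or 3 and 1 clusters, and HOXB4 had none called and 1. With clusters counted once per gene, an alternative chosen after seeing the data, the log2 ratio of the list was −2.54 (−3.63 to −1.59). Interactions with at least 1 end in a HOX gene cluster numbered 49 in H1 and 1 in GM12878 for HOXA, 76 and 31 for HOXB, 93 and 9 for HOXC, and 35 and 6 for HOXD. Interactions with both ends in the same cluster numbered 11, 11, 20 and 1 in H1 and 0 in GM12878 for each. The median log2 ratio of the HOX genes was −1.17, below that of every random list (percentile 0). The size of the HOX contrast depended on the GM12878 list used, since in 10-kb bins the HOX promoters had 117 distinct interactions in H1, 18 in the GM12878 list used here and 55 in the list filed under GM12878 replicate 1.

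Alpha protocadherins, neuronal cell surface proteins each driven by its own promoter, had 28 promoter interactions in H1 and no called interaction in GM12878 over 15 genes. PCDHA12 and PCDHAC1 had 8 each in H1, in 3 clusters each. The GM12878 share of the list was 0% with an upper 95% limit of 12.3%, against 54.7% over all promoters, and 8 of the 15 members had a call in H1. The median log2 ratio of −1.07 lay at percentile 0.03.

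Lists for other cell types and for housekeeping genes had intervals that held 0 with the counts used here. Under alternatives the liver interval lay below 0 with neighbouring bins (−1.60 to −0.03) and with summed reads (−1.75 to −0.97). The T cell interval lay above 0 with summed reads (1.34 to 1.97). T cell genes had 11 interactions in GM12878 and 3 in H1 over 18 genes (log2 1.60, −0.32 to 4.08). TCF7 had 3 and CD5 had 2 in GM12878 with none called in H1, and BCL11B and CD4 had 1 each in H1 with none called in GM12878. Further T cell genes higher in GM12878, named after their values were seen, included LCK with 2 against none called and CD6 with 2 against 1. Myeloid and erythroid genes had 4 in GM12878 and 5 in H1 over 14 genes (log2 −0.60, −2.93 to 1.62), with MPO at 2 and CEBPE at 1 in H1 and CD14 at 2 and CSF1R at 1 in GM12878, none of them called in the other line. HBA1, with 1 in H1 and none called in GM12878, and S100A9, with 1 in each, were also higher in H1 and were named after their values were seen. Liver genes had 4 in GM12878 and 8 in H1 over 17 genes (log2 −1.27, −3.46 to 0.63), with APOA2 at 3 and APOB at 2 in H1 and none called in GM12878, and FGB at 2 in GM12878 and 1 in H1. APOA1 and AHSG had 1 in each line and were named after their values were seen. Housekeeping genes had 45 in GM12878 and 35 in H1 over 24 genes (log2 0.09, −0.58 to 0.77). ACTB had 11 in GM12878 and 15 in H1, EEF1A1 had 6 and 7, RAB7A had 3 and none called, and the bin shared by TBP and PSMB1 had 5 and none called. ACTB was counted at its outermost annotated start, position 5563784 of a gene annotated from 5527151, and starts further inside were not counted. Without the member with most interactions the log2 ratio of the list was 0.49 (−0.35 to 1.37). Of the housekeeping genes 7 were higher in GM12878, 9 in H1 and 8 had no called interaction.

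Among all protein-coding genes, the largest excess in H1 lay at histone genes of chromosome 6. These are related gene copies, and whether reads shared between them add to their interactions was not tested. The bin of H2AC15 and H2BC15 had 30 interactions in H1 (20.2 to 42.9) and 9 in GM12878 (4.12 to 17.1), that of H1-5 and H2AC16 had 28 and 12, that of H3C11 and H4C13 had 23 and 6, that of H2AC14 and H3C10 had 32 and 17, and H2BC14 had 26 and 13. With neighbouring interactions counted once as a cluster, an alternative chosen after seeing the data, H2AC15 had 8 clusters in H1 and 5 in GM12878, H1-5 had 6 and 4, H3C11 had 7 and 4, H2AC14 had 6 in each line, and H2BC14 had 6 and 7. Outside the histone genes, IER5L had 20 interactions in H1 and 5 in GM12878, or 5 and 2 clusters. FZD5, a receptor for WNT ligands, had 17 and 1, or 2 and 1 clusters, and GSX1, a homeobox gene of the developing brain, had 15 interactions in 5 clusters and none called in GM12878.

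In GM12878 the largest excess lay at SIPA1L1, with 23 interactions (14.6 to 34.5) and none called in H1. GCSAM, a germinal centre B cell signalling protein, and MAML2, a co-activator of Notch, each had 19 there with none called in H1. FCMR, the receptor for IgM, had 17 and 1, IRF2BP2 had 17 and 2, and ADAMTS6 had 24 and 8. HLA-DRA and PAX5 were also among the 8 genes of largest excess in GM12878. Counted as clusters, SIPA1L1 had 8, MAML2 5 and GCSAM 3 in GM12878, and the GM12878 and H1 numbers were 6 and 1 for FCMR, 5 and 2 for IRF2BP2, 5 and 2 for PAX5, 4 and 2 for HLA-DRA and 5 and 4 for ADAMTS6.

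**Figure D3:**
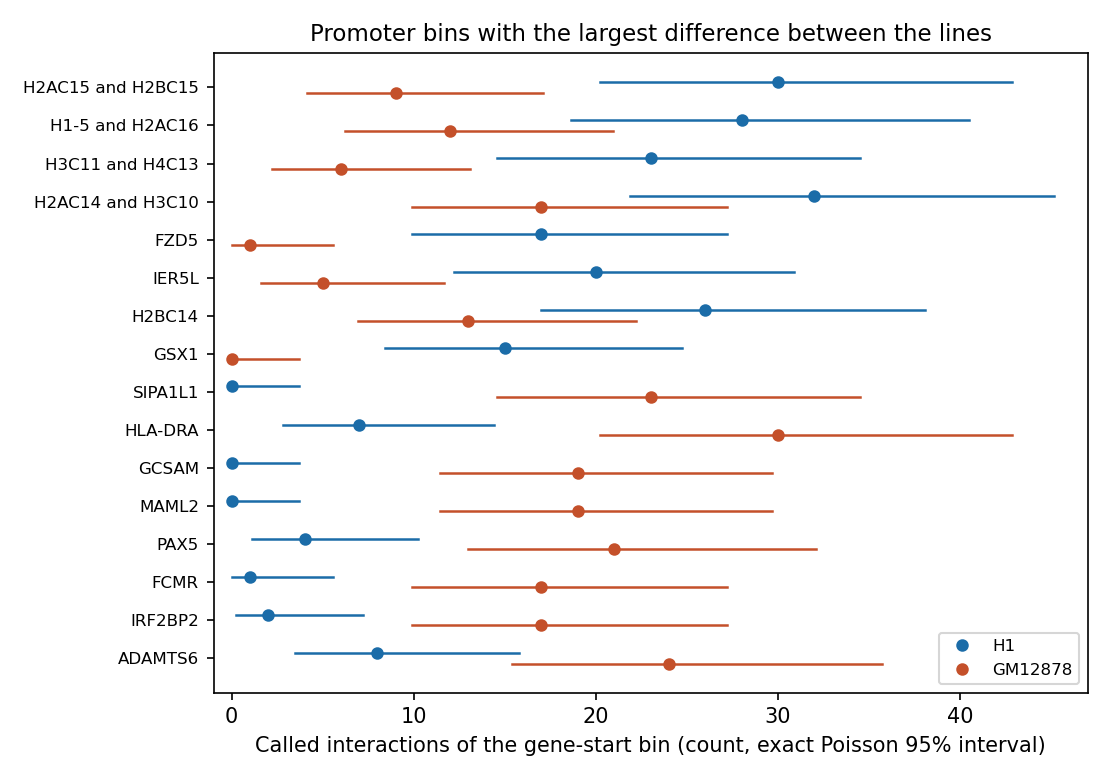
Called interactions per gene-start bin in H1 (blue) and GM12878 (red) for the 8 promoter bins with the largest excess in each line, with exact Poisson 95% intervals as bars. Histone genes with 23 to 32 interactions in H1 lead one group, and SIPA1L1 with 23 in GM12878 and 0 in H1 leads the other.

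The last comparison set the GM12878 list of 5-kb bins beside the list of 10-kb bins filed under GM12878 replicate 1. Of the interactions in the 5-kb list, 84.0% (83.7 to 84.3%) had a partner in the 10-kb list with both ends within 1 bin of 10 kb, and those without one were short, with a median of 55 kb against 160 kb. Of the 42459 interactions in the 10-kb list, 77.7% (77.3 to 78.1%) had a partner in the 5-kb list. Whether the lists rest partly on the same reads is unknown, so these shares do not measure agreement between separate libraries. For B cell promoters the 10-kb list held 120 interactions, against 105 in the GM12878 and 26 in the H1 list put into bins of the same size. The NF-κB response promoters gave 84, 81 and 16 in the same order, developmental transcription factors 33, 23 and 144, and pluripotency genes 15, 20 and 62. For alpha protocadherins neither GM12878 list held an interaction, while H1 had 27.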

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

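Counting clusters once per gene, counting pairs once per list, leaving out members of the further lists and the limits on span of 2 Mb and 20 kb were chosen after seeing the data. No paired analysis was possible because each line has 1 list of 5-kb bins without values per replicate, and for the same reason no replicate could be left out. The list of 10-kb bins filed under GM12878 replicate 1 has no counterpart in H1. CTCF motifs, gene expression with its count-table alternatives, and bins of all annotated transcript starts were not run, and a limit to autosomes removes no pair. Of 77 gene list values under alternatives, 75 stayed within the interval of the reported value, 2 moved and 0 reversed. Both were B cell log2 ratios, at 3.75 with summed reads and 1.90 with clusters, and remained above 0. Alpha protocadherins had no called interaction in GM12878, which most alternatives cannot change. The T cell, myeloid and erythroid, and liver intervals were wide. For these lists, staying within the interval does not show a stable value. Of 284 values over 58 named genes, 266 stayed, 10 moved and 8 reversed. Here a value stayed if it lay within the exact binomial interval of the gene's main share and was not counted as reversed. For genes with few interactions that interval covers most possible shares, so staying within it does not show a stable value. With neighbouring bins APOA2, CEBPE and TNFAIP2 gained interactions in GM12878, where none had been called, and still counted as stayed. Of 18 values of the 6 further lists, 16 stayed, 2 moved and 0 reversed. The liver interval excluded 0 with neighbouring bins (−1.60 to −0.03) and with summed reads (−1.75 to −0.97), and the T cell interval with summed reads (1.34 to 1.97), which takes reads as independent. The cause of the moves was not tested, except that looser matching and wider promoters must raise a share.

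At a false discovery rate under 0.001 the ratio of GM12878 to H1 interactions was 1.46, and the share with a promoter in H1 was 23.3%. The shared share at that rate was 42.6% for H1 and 34.4% for GM12878 with the stricter rate in the own list, and 29.7% for GM12878 with it in both. Without pairs that stand alone, the ratio was 1.44, the H1 median span 160 kb and the GM12878 shared share 29.4%. With equal numbers of pairs, 34.2% of H1 and 33.6% of GM12878 interactions were shared. In identical bins 22.6% and 16.0% were shared, and within 2 bins 44.8% and 36.6%. Promoter shares in H1 and GM12878 were 41.8% and 39.9% with neighbouring bins and 35.8% and 32.1% with all annotated genes. The 5-kb GM12878 list was found in the 10-kb list for 71.9% in identical bins, 87.9% within 2 bins and 89.1% at spans of at least 20 kb. The reverse gave 54.0%, 83.6% and 76.9%, and 76.6% at the stricter rate.

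The 8 reversals are given as the GM12878 percent of the gene's interactions. With neighbouring bins these were EBF1 64.7, EEF1A1 57.1, HLA-DPA1 63.6, HOXB4 54.5 and TRAF1 75. With clusters they were FGB 50 and H2BC14 53.8, and with summed reads CD40 91.5.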

Other observations

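The 6 gene lists described first, the histone gene values, the chromosome 8 contacts and the tests of a rearrangement, of mitochondrial copies and of lists without their leading members were chosen after the results were seen. Genes for WNT ligands and their frizzled receptors had 47 promoter interactions in H1 and 6 in GM12878 over 29 genes, a log2 ratio relative to all promoters of −3.24 (−4.76 to −2.01). FZD5 had 17 of those in H1 and WNT9A, a WNT ligand, had 8 with none called in GM12878, and without both genes the ratio was −2.41 (−4.17 to −0.97). With clusters counted once per gene the list had 18 and 5 (−2.07, −3.85 to −0.59). Of the 29 genes 14 were higher in H1, 2 in GM12878 and 13 had no called interaction. Genes of neuronal signalling had 29 in H1 and 4 in GM12878 over 19 genes (−3.13, −5.10 to −1.62). GAD1, which makes the transmitter GABA, had 16 in H1 and 3 in GM12878, and GRIN2A, a glutamate receptor subunit, had 7 and none called. The contrast rested on few genes, since 5 members were higher in H1, 1 in GM12878 and 13 had no called interaction. Without GAD1 and GRIN2A the list had 6 and 1 (−2.86, −8.38 to 0.18), and with clusters the interval also held 0 (−4.33 to 0.20). Ligands and antagonists of the BMP, TGF-beta and FGF families had 19 in H1 and 23 in GM12878 (0.00, −0.94 to 0.96), and FGF8 had 4 in H1 and 10 in GM12878. Without FGF8 and TGFB3 they had 13 and 6 (−1.39, −3.07 to 0.11). Cell cycle genes had 55 in H1 and 39 in GM12878 over 30 genes (−0.77, −1.40 to −0.15), but CCND2, at 19 and 9, and CCND1, at 12 and 2, carried that difference. Without both of these cyclin genes the list had 24 and 28 (−0.05, −0.89 to 0.80).

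Cytokine receptor genes had 30 promoter interactions in GM12878 and 3 in H1 over 21 genes (3.05, 1.36 to 5.41), and 12 members were higher in GM12878 against 1 in H1, FAS. IL10RA and IL10RB, the chains of the interleukin-10 receptor, had 5 each in GM12878 and 1 each in H1, and IL21R had 4 and none called. Interferon response genes had 18 interactions in GM12878 and none called in H1 over 25 genes, a GM12878 share of 100% (81.5 to 100%). These lay at 8 genes, among them IFIT1, IFIT3, OAS1 and IFI44 with 3 each.

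The 53 histone genes on chromosome 6, in 34 bins, met 265 distinct interactions in H1 and 137 in GM12878, and 60.8% of the H1 ones (54.6 to 66.7%) had a histone gene bin at both ends, against 54.0% in GM12878 (45.3 to 62.6%). Reads shared between related histone gene copies were not tested as a source of these interactions. On chromosome 8, GM12878 had 15 interactions between 127175001 to 127310000 and 129545001 to 129555000, with MYC between the ends, spanning 2240 to 2375 kb with 9 to 17 reads each, while H1 had none called and the 10-kb GM12878 list held 10. The MYC promoter had 11 interactions in GM12878 and 4 in H1.

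A small set of interactions spanned more than 2 Mb, 143 in H1 and 193 in GM12878. The pairs with most reads were, on chromosome 16, the bins at 34585001 to 34590000 and 46390001 to 46395000, with 762 reads in H1 and 1025 in GM12878 and no gene of the name stems searched at either end, and, on chromosome 5, the bins at 100050001 to 100055000 and 134925001 to 134930000, both beside copies of mitochondrial sequence, with 541 and 2797 reads. A rearrangement carried by 1 line is argued against only for the pairs called in identical bins in both lines, 51.0% of the H1 set (42.6 to 59.5%) and 37.8% of the GM12878 set (31.0 to 45.1%), and mitochondrial copies at both ends covered 6.29% and 6.22%. Reads shared between related gene copies may account for part, as genes of the same name stem lay at both ends of 27.3% in H1 and 31.1% in GM12878, above the highest of 100 exchanges of right ends, 17.5% and 17.1%, although pairs from 500 kb to 2 Mb also exceeded theirs, with 12.4% against 6.19% in H1 and 6.89% against 2.23% in GM12878. The remaining far pairs stay open, among them the 15 on chromosome 8 called in GM12878 alone, for which a rearrangement in that line is not excluded, and no biological explanation was tested.

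Developmental transcription factors had more promoter interactions in H1. Repeated counting of a contact in neighbouring bins is argued against as the cause, since with clusters counted once the log2 ratio was −2.90 (−4.03 to −1.93). A difference between the lines in accessibility of these promoters, on which HiCAR reads depend, was not tested and could give the same picture, as could a difference in contacts between embryonic stem cells and B-lymphoblastoid cells.

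The GM12878 share of interactions differed between chromosomes, from 49.8% on chromosome 22 to 69.8% on chromosome 8. It was lower on gene-dense chromosomes, with a Spearman rho across 22 chromosomes against protein-coding genes per Mb of −0.87 (two-sided permutation p = 4.0e-05, adjusted over 2 relations 8.0e-05) and a Pearson r of −0.50 (p = 0.00984, adjusted 0.0197). Without chromosomes 17 and 19, the farthest from the median density, rho was −0.87 (permutation p = 2.0e-05, the smallest these permutations can give) and r −0.73 (p = 0.0002), so the share may follow gene density. A gain or loss of whole chromosomes cannot be told apart from this, since the shares of pairs with and without a promoter had a rho of 0.36 across chromosomes (permutation p = 0.102, adjusted 0.102), between the bounds set for either outcome, and an r of 0.46 (p = 0.0351, adjusted 0.0351) that was 0.18 (p = 0.459) without the 2 chromosomes of most extreme promoter share. The cell lines differ in every library, so a biological difference between them stays open.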
